A study of Mus musculus with 12 samples.

How the data were processed

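The study measured mRNA in 12 samples of NMuMG spheroids, 4 each in serum-free medium, with GDF11 and with TGFB1, on 1-colour Illumina beadchips hybridized with biotin-labelled cRNA. Each sample is a biological replicate made from 2 pooled wells. The deposited non-normalized table gives for each probe and array the bead signal, an intensity on a linear scale with no background subtracted, per the file headers. Per the file headers it also holds a detection p-value for signal above negative control beads, the number of beads as another measure, and the bead standard error, again an intensity. The authors' processed values are on a log2-like scale. The submitters' notes name lumi without a version or role, and the transformation and log base are not given in the sources used here. Each column of the authors' processed values kept the rank order of the raw intensities of its array (Spearman correlation 1), and column medians lay between 6.90 and 6.92.

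The raw table held 25697 probes and 20692 blank lines. Its 18138 symbols were matched to a RefSeq gene table (GRCm38.p6, used for names alone): 14307 were current, 2906 matched a single gene by synonym and 904 were kept as the array gives them. Another 31 probes carried symbols that a spreadsheet had turned into dates and stayed unnamed. No coordinates are given, because the files name no genome build. All columns were matched to samples by the names in the labels, and no pair of arrays was identical.

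R 4.3.3 with limma 3.58.1 was used for all tests and Python 3.11.15 with matplotlib 3.10.9 for drawing. Intensities were corrected and normalized with neqc, which estimates background from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. The offset pulls changes of dim genes toward 0. Probes with a detection p under 0.05 on at least 4 of 12 arrays were kept (12680), and for the 2490 genes with several such probes the probe with the highest mean was used. This left 9134 genes, of which 18 had no name. A linear model with 1 mean per group was fitted to all 12 arrays with lmFit and eBayes, and each of the 3 comparisons was adjusted by Benjamini-Hochberg, with calls at an adjusted p under 0.05. Replicate numbers were not treated as pairs, since 4 of 12 arrays correlated best with their own number in another group. A gene not detected in the lower group is given as at least N-fold, its fold being taken against the lowest detected level of the arrays, at 4.43 to 4.76 on the log2 scale. Mean beads per probe were 39.6 ± 0.44 in serum-free medium, 39.3 ± 0.60 with GDF11 and 36.3 ± 1.34 with TGFB1 (SD, n = 4, two-sided exact permutation p = 0.6 and 0.0286 against serum-free medium, and 0.0286 for TGFB1 against GDF11). The correlation of replicate arrays was 0.949 to 0.995.

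Gene lists, tests and the rule for named genes were fixed before the data were examined. The 20 function lists were SMAD2/3 targets, BMP and SMAD1/5 targets, TGF-beta family ligands and receptors, mesenchymal genes, epithelial junction genes, matrix and integrin genes, actin genes, YAP/TEAD targets, immediate-early genes, G1 and growth arrest genes, S and G2/M genes, apoptosis genes, cholesterol genes, hypoxia and glycolysis genes, unfolded protein response genes, interferon-stimulated genes, NF-kappaB and cytokine genes, NRF2 targets, Wnt and Notch genes, and EGF, FGF and MET genes. The 6 marker lists were mammary luminal and basal cells, fibroblasts, endothelium, leukocytes and adipocytes. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation. This left 22 lists, as fibroblast, endothelial, leukocyte and adipocyte markers had 4, 3, 2 and 3 tested genes and were not tested. Some genes stand in more than 1 list.

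Named genes were, per comparison, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and that were detected on all 4 arrays of the higher group. To these were added 19 fixed genes and up to 4 members with the smallest p of each called list. Of the fixed genes, Smad7 was detected on 1 array, Id4 and Bambi on none, and Fn1 and Gdf11 had no probe in the table, so they were not tested. Chosen after their values were seen were Rasl11b, Tuft1, Arid5b, Twist2, Mmp13, Lamc1, Msx1, Hey1, Tgfbr2, Acvr2b, Dusp1, Dusp6, Zfp36, Lasp1, Anln, Il33, Bcl3, Krt8 and Krt18, which are members of fixed lists, and all genes named under other observations that the report does not name.

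The split into dim and bright arrays was made at the largest gap in mean raw intensity, and the brightness term, the fits on bright or dim arrays alone, and the fits that join the term with another choice were added after seeing the data. Principal components of the normalized values took 63.5% and 13.4% of the variance. Other settings tried were no background correction, an offset of 50, median scaling, cyclic loess, the authors' processed values, no filter, a strict filter, all probes kept, only the groups compared, trended robust variances, array weights, a replicate block, a minimum of 1.5-fold, an adjusted p under 0.01, other list tests, and leaving out each array. Where a setting left 1 array in a group, that array was assumed to vary like the other groups. A block for the chip was not run because the files name no chip.

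The model was tested on simulated data of 9134 genes in which 200 were changed. Without a brightness shift, changes of 0.5, 1 and 2 on the log2 scale were recovered in 55.2%, 94.0% and 100% of cases for GDF11 against serum-free medium, with 8 false calls (4.60% of calls). For TGFB1 they were recovered in 44.8%, 97.0% and 100%, with 12 false calls (6.94%). With the measured brightness shift added, the model without the term recovered 28.4%, 89.6% and 97.0% for GDF11 (8 false calls, 5.30%) and 43.3%, 88.1% and 93.9% for TGFB1 (59 false calls, 28.2%). The model with the term recovered 37.3%, 92.5% and 98.5% for GDF11 (11 false calls, 6.75%) and 20.9%, 88.1% and 98.5% for TGFB1 (4 false calls, 2.82%). The simulated shift of a gene was the same in every group, which is what the model with the term assumes, and the noise was independent. The few false calls with the term thus follow in part from the simulation and do not show its error on the real arrays. The 200 changed genes were also fewer than the genes called against serum-free medium on the real arrays. In the simulation of TGFB1 against serum-free medium, a list of 30 genes shifted by 0.5 was called by camera among 22 lists, and no other list was.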

Results

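Expression was measured on 12 Illumina beadchip arrays of RNA from spheroids of NMuMG, an epithelial line derived from the normal mouse mammary gland. The spheroids grew for 6 days on Matrigel, a basement membrane extract, from 5000 cells per well, with fresh growth medium on day 4. They then spent 4 h in serum-free medium, with 250 ng/mL of GDF11 or with 50 ng/mL of TGFB1. GDF11 and TGFB1 are secreted ligands of the TGF-beta family that signal through SMAD2 and SMAD3, and their doses here differed. Each of the 3 groups held 4 biological replicates, and the RNA of 2 wells was pooled for each. The arrays reported 25697 probes, of which 12680 rose above background on at least 4 arrays, and these gave 9134 genes for testing. Signal passed the detection threshold for 41.2% to 49.6% of probes per array, and the 4 arrays per group limit the precision of every value.

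The arrays fell into 2 sets by mean raw intensity, in scanner units. Serum-free replicates 1, 2 and 4 and GDF11 replicate 1 lay between 149 and 165, while serum-free 3, GDF11 2, 3 and 4 and all 4 TGFB1 arrays lay between 255 and 310. These sets are called dim and bright here. Mean intensity was 189 ± 62.8 in serum-free medium, 251 ± 68.5 with GDF11 and 298 ± 7.53 with TGFB1 (SD, n = 4 each). A two-sided exact permutation test gave p = 0.286 for GDF11 and p = 0.0286 for TGFB1 against serum-free medium, the latter the smallest p that 4 against 4 arrays allow. After quantile normalization, and with the groups in the model, limma called 4494 of the 9134 genes for dim against bright arrays at a Benjamini-Hochberg adjusted p under 0.05. Of these, 2073 were higher and 2421 lower on bright arrays, and the median absolute shift over all genes was 0.35 on the log2 scale. In a model that also held the groups, the keratin genes Krt8 and Krt18 were higher on bright arrays by 1.03 ± 0.10 and 1.15 ± 0.16 on the log2 scale (SE), Id2 by 1.69 ± 0.13 and Cdh1 by 0.87 ± 0.12, while Kitl was lower by −2.48 ± 0.10 (limma adjusted p = 8.29e-06, 9.38e-05, 1.6e-06, 0.0001 and 3.26e-08). Dio3 (−0.17, adjusted p = 0.348) and Snai1 (0.31, adjusted p = 0.219) did not pass. The GDF11 effect differed between dim and bright arrays for 1 gene (886 at an unadjusted p under 0.05). That comparison rests on 1 dim GDF11 array and 1 bright serum-free array, so it cannot show that the effect was alike on both sets. Because many genes shifted with brightness, a model with a term for dim against bright arrays, called the brightness term, was fitted too. This model takes the shift of a gene to be the same in every group. The value with the term is given below for counts, for called lists and for called genes that it moved by over 1.5 times. The term was added after the split had been seen.

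**Figure D1:**
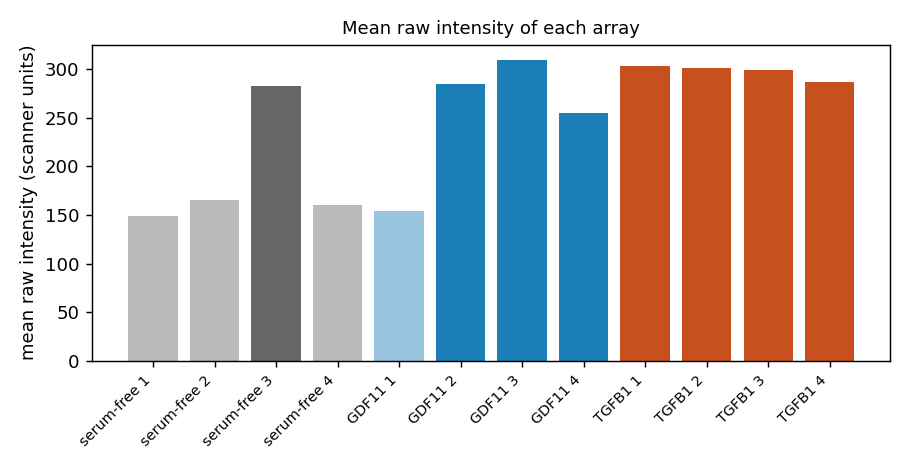
Mean raw intensity in scanner units for each of the 12 arrays, grouped by treatment, with pale bars for the 4 dim arrays. The dim arrays lie between 149 and 165 and the bright arrays between 255 and 310, and no TGFB1 array is dim.

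GDF11 was compared with serum-free medium to find the genes the ligand changes within 4 h. Lmcd1, a LIM-domain cofactor of transcription, rose 17.8-fold (log2 change 4.15 ± 0.18, SE, n = 4 per group, limma adjusted p = 2.02e-08). The tight junction gene Cldn4 was not detected in serum-free medium and was at least 5.41-fold higher with GDF11 (adjusted p = 2.68e-07). The cytokine gene Il11 rose 5.77-fold (2.53 ± 0.26, adjusted p = 5.17e-05) and Bhlhe40, a transcriptional repressor of the clock, 4.59-fold (2.20 ± 0.14, adjusted p = 4.14e-07). Dio3, which inactivates thyroid hormone, was 9.23-fold lower (−3.21 ± 0.14, adjusted p = 2.27e-08), and Depp1, a FOXO target, was 6.12-fold lower (−2.61 ± 0.16, adjusted p = 4.14e-07). Among other large rises were those of Rhob (2.64), Mab21l4 (2.50), Spsb1 (2.38), Arid3a (2.16), Fam210b (2.14) and Sphk1 (2.09) on the log2 scale. The large falls included those of Shh, the sonic hedgehog ligand (−1.93), Ugt2b35 (−1.89), Kcnk5 (−1.84), Igfbp5 (−1.76), Clec2d (−1.76), LOC100048721 (−1.72) and Akr1c19 (−1.69), and Ppp1r3c was at least 2.74-fold lower. "At least" marks a gene not detected in the lower group, whose fold was taken against the detection floor of the arrays. A second Shh probe gave −0.08. Shh was detected on 2 of the 4 GDF11 arrays and Arid3a on 2 of the 4 serum-free arrays, so the sizes of these changes are uncertain too.

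In all, limma called 907 of 9134 genes (9.93%), 437 higher and 470 lower with GDF11, and 2690 genes had an unadjusted p under 0.05. The 4 arrays of each group did not overlap for 10.7% of genes, where chance gives 2.86%. Adding the brightness term gave 953 called genes, 661 of them among the 907, and of the 202 genes changed at least 2-fold 191 kept their call. Lmcd1, Il11, Dio3 and Depp1 then changed by 3.91, 2.68, −3.12 and −2.69, and Rhob by 1.92. Without GDF11 1 the count with the term was 313. The bright arrays alone, 1 serum-free against 3 GDF11, gave 563 calls, and the dim arrays alone, 3 against 1, gave 6 calls with 1165 genes under an unadjusted p of 0.05. The fold changes of these 2 sets correlated across genes with r = 0.553. The count moved with single arrays: it was 571, 512, 2833 and 503 without serum-free 1, 2, 3 or 4, and 3367, 517, 496 and 444 without GDF11 1, 2, 3 or 4. Serum-free 3 is the only bright serum-free array and GDF11 1 the only dim GDF11 array. Without either, brightness follows the groups more closely, so 2833 and 3367 cannot be read as a larger GDF11 response.

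**Figure D2:**
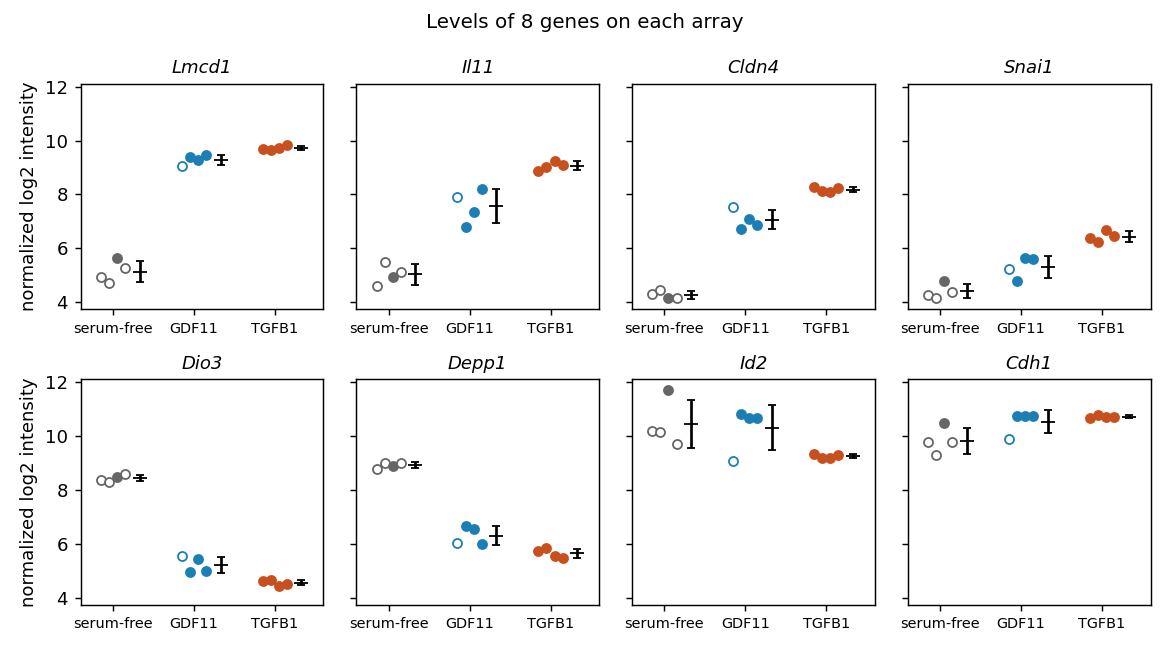
Normalized log2 intensity of 8 genes on each of the 12 arrays, with open points for the dim arrays and black marks for the group mean ± SD (n = 4). Lmcd1, Il11, Cldn4 and Snai1 sit higher and Dio3 and Depp1 lower with both ligands, while the Id2 and Cdh1 values of dim and bright arrays differ within groups.

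Known targets of SMAD2 and SMAD3 rose with GDF11: of 29 tested, 18 rose and 3 fell, or 19 and 4 adjusted over the list alone (median log2 change 0.64, camera adjusted p = 1.61e-09, and adjusted p = 0.0237 with an estimated correlation). Pmepa1, a feedback inhibitor of the pathway, rose by 1.97 ± 0.22, Skil, a SMAD corepressor, by 0.88 ± 0.18, and Junb and the growth factor gene Pdgfb by 1.46 and 1.83. A second Pdgfb probe gave 0.34. The 3 that fell were Rasl11b (−1.57), a RAS-like GTPase, Tuft1 (−0.72, and −0.44 with the brightness term) and Arid5b (−0.93), a chromatin regulator, and the median with the term was 0.75. Inhba, which encodes the activin A subunit, did not pass (−0.18, adjusted p = 0.356). Of 22 genes associated with mesenchymal cells, 6 rose and none fell, or 13 and 0 adjusted over the list alone (median 0.47, adjusted p = 2.79e-05, and adjusted p = 0.048 with an estimated correlation, but adjusted p = 0.101 with an estimated correlation and the brightness term). Snai1, which represses Cdh1 transcription, rose by 0.91 ± 0.20 (adjusted p = 0.0102) without the term and by 0.75 with it, but it did not pass on bright arrays alone (0.56, adjusted p = 0.265), under cyclic loess (0.41, adjusted p = 0.189) or with the authors' processed values (0.21, adjusted p = 0.0701). Itga5, the fibronectin receptor subunit, rose by 1.09, Ets1 by 0.96 (its other probes gave −0.03 and 0.56) and Mmp14 by 0.47. The list's median was 0.32 with the brightness term, 0.21 on bright arrays and 0.44 on dim arrays. Of 29 matrix and integrin genes 9 rose and none fell, or 13 and 2 adjusted over the list alone, among them Itgb6 (1.13), Lamb3 (1.04) and Thbs1 (0.97), which under cyclic loess did not pass (0.53, adjusted p = 0.0641). Pmepa1, Snai1 and Thbs1 were detected on 1 of the 4 serum-free arrays, so their changes were measured against a level near background and their sizes are uncertain. The median of the 29 matrix and integrin genes was 0.29 (adjusted p = 6.3e-05, but adjusted p = 0.0627 with an estimated correlation), and 0.43 with the term.

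Camera called 4 further lists with GDF11. Of 27 NF-kappaB and cytokine genes 8 rose and 1 fell, or 11 and 2 adjusted over the list alone (median 0.23, adjusted p = 0.00356, but adjusted p = 0.0627 with an estimated correlation). The chemokine genes went apart: Ccl7 rose by 1.43 and Cxcl16 by 0.57, while Cxcl1 fell by 1.40. Of 25 immediate-early and AP-1 genes 6 rose and none fell, or 8 and 0 adjusted over the list alone (median 0.28, adjusted p = 0.00519, and adjusted p = 0.048 with an estimated correlation, but adjusted p = 0.101 with an estimated correlation and the brightness term), with Fos at 1.40, Ier3 at 0.85 and Egr2 at least 2.59-fold higher. Of 31 actin and adhesion genes 4 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.32, adjusted p = 0.00546, but adjusted p = 0.0627 with an estimated correlation). Actn1 rose by 0.91 and Pdlim7 by 0.78, and Rnd3, which opposes RhoA signalling, fell by 1.03. Of 28 TGF-beta family ligands, receptors and modulators 6 rose and 4 fell, or 11 and 5 adjusted over the list alone (median 0.25, adjusted p = 0.0234, but adjusted p = 0.113 with an estimated correlation). The type I receptor genes Acvr1 and Tgfbr1 rose by 1.5 and 1.49 and Tgfb1 itself by 0.75, while Bmp4 fell by 1.34, Gdf15 by 0.87, Lefty1 by 0.73 and Tgfbr2 by 0.47. This last list was not called without GDF11 1 (adjusted p = 0.0922) or on bright arrays alone (adjusted p = 0.159). The medians of these 4 lists were 0.24, 0.15, 0.18 and 0.27 once the brightness term was in the model.

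The cell cycle inhibitor genes Cdkn2b and Cdkn1a rose by 0.87 ± 0.15 (adjusted p = 0.00286) and 0.47 ± 0.12 (adjusted p = 0.025) with GDF11, and Myc, detected on 2 of 4 arrays in each group, did not pass (−0.15, adjusted p = 0.595). Cdh1, the epithelial cadherin, and Vim, the mesenchymal intermediate filament, did not pass either (0.71, adjusted p = 0.075, and 0.50, adjusted p = 0.114), and with the brightness term they stood at 0.27 and 0.20. Both passed without serum-free 3 (adjusted p = 0.0071 and 0.00668) or without GDF11 1 (0.00515 and 0.0297). The Cdkn1a call ended without serum-free 1 or 4 or GDF11 2, 3 or 4 (adjusted p 0.0517 to 0.0768) and the Tgfbr2 call without serum-free 4 or GDF11 2 or 3 (0.0509 to 0.0584). That of Arid5b ended without serum-free 2 or 4 or GDF11 2, 3 or 4 (0.0712 to 0.0874), and with the term (−0.55, adjusted p = 0.0545), and that of Tuft1 without serum-free 1, 2 or 4 or GDF11 2, 3 or 4 (0.0546 to 0.075). On bright arrays alone, with 1 serum-free array, Rnd3 (−0.74), Thbs1 (0.73), Mmp14 (0.42), Tuft1 (−0.45) and Arid5b (−0.45) did not pass (adjusted p 0.0562 to 0.101). Under median scaling, which moved the median of all genes by 0.39, Tgfbr2 stood at 0.09, below that median but above 0.

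Of the other 15 lists tested for GDF11 without the brightness term, camera called none at an adjusted p under 0.05. The medians and adjusted p were −0.13 and 0.345 for BMP targets, 0.15 and 0.274 for epithelial junction genes, 0.08 and 0.334 for YAP/TEAD targets, −0.14 and 0.563 for G1 and growth arrest genes, and −0.12 and 0.12 for S and G2/M genes. They were 0.05 and 0.679 for apoptosis genes, 0.13 and 0.418 for cholesterol genes, 0.09 and 0.496 for hypoxia and glycolysis genes, −0.03 and 0.638 for unfolded protein response genes, and −0.27 and 0.274 for interferon-stimulated genes. For NRF2 targets they were 0.08 and 0.714, with the test pointing down, for Wnt and Notch genes 0.18 and 0.221, and for EGF, FGF and MET genes 0.08 and 0.321. The mammary marker lists gave 0.69 and 0.336 for luminal cells and 0.50 and 0.22 for basal cells, with 7 genes tested in each.

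TGFB1 was compared with serum-free medium in the same way, and its strongest responders were largely those of GDF11. Lmcd1 rose 24.1-fold (log2 change 4.59 ± 0.18, SE, n = 4 per group, limma adjusted p = 2.67e-09), Il11 16.3-fold (4.02 ± 0.26, adjusted p = 2.58e-07) and Cldn4 at least 11.7-fold (adjusted p = 3.44e-09). Ass1, the arginine-making enzyme argininosuccinate synthase, rose by 3.28 ± 0.14 (adjusted p = 4.37e-09), and the TNF receptor family gene Cd40 was at least 7.14-fold higher, though its other probes gave log2 changes of 0.71 to 1.21. Dio3 was 14.7-fold lower (−3.88 ± 0.14) and Depp1 9.66-fold lower (−3.27 ± 0.16). Further rises on the log2 scale were those of Mab21l4 (3.52), Rhob (3.03), Sdc3 (2.97), Spsb1 (2.96), Bhlhe40 (2.89) and Sphk1 (2.78). Further falls were those of Kitl, the KIT ligand (−2.69), Clec2d (−2.56), the serine protease gene Tmprss2 (−2.55), Akr1c19 (−2.53), Ugt2b35 (−2.42), Dbp (−2.37), LOC100048721 (−2.37) and Neu2 (−2.33). Kitl was detected on 1 of the 4 TGFB1 arrays, so the size of its fall is uncertain.

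In all, limma called 3140 genes (34.4%), 1436 higher and 1704 lower with TGFB1, and 4263 had an unadjusted p under 0.05. The groups did not overlap for 33.5% of genes, where chance gives 2.86%. With 3 of the 4 serum-free arrays dim and every TGFB1 array bright, brightness can raise this share too, so it cannot be read as the ligand's alone. With the brightness term 1448 genes were called, 724 in each direction, and 1116 of them were among the 3140. Of the 751 genes changed at least 2-fold, 508 kept their call. The term left Lmcd1 at 4.22, Il11 at 4.26, Dio3 at −3.75 and Depp1 at −3.39, and moved Kitl to −0.83, Rhob to 1.94 and Neu2 to −1.58. The bright arrays alone, with 1 serum-free array, gave 1558 calls, and no TGFB1 array was dim. Without serum-free 1 or 2 the count was 2046 or 2061.

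SMAD2/3 targets also rose with TGFB1: 21 of 29 rose and 3 fell, or 22 and 3 adjusted over the list alone (median 0.79, camera adjusted p = 7.95e-09, and adjusted p = 0.0305 with an estimated correlation). Snai1 rose by 2.03 ± 0.20 (adjusted p = 7.29e-06), the metalloproteinase inhibitor gene Timp3 by 2.41, Pmepa1 by 1.99, Skil by 0.73 and Junb by 1.35, while Rasl11b (−1.60), Tuft1 (−1.20) and Arid5b (−1.42) fell again. The term put Skil at 1.16, Rasl11b at −0.98, Tuft1 at −0.78 and Arid5b at −0.83. Of 22 mesenchymal genes 15 rose and 1 fell, or 17 and 1 adjusted over the list alone (median 0.60, adjusted p = 1.3e-05, but adjusted p = 0.0592 with an estimated correlation). Itga5 rose by 1.91 and the actin-binding gene Cald1 by 1.29 (0.81 with the term), and the gene that fell was Twist2 (−1.04, and −0.26 with the term, adjusted p = 0.51). Of 29 matrix and integrin genes 16 rose and 2 fell, or 18 and 2 adjusted over the list alone (median 0.54, adjusted p = 1.32e-05, but adjusted p = 0.0769 with an estimated correlation). Itgb6 rose by 1.59 and Lamb3 by 1.55, and the matrix collagenase gene Mmp13 (−0.88) and the laminin gene Lamc1 (−0.59) fell. With the brightness term these 3 medians were 1.12, 0.56 and 0.71.

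Another 4 lists were called for TGFB1, each with members on both sides. Of 28 TGF-beta family genes 14 rose and 5 fell, or 15 and 5 adjusted over the list alone (median 0.42, adjusted p = 0.0155, but adjusted p = 0.111 with an estimated correlation): Acvr1 rose by 2.09, Tgfbr1 by 1.33, Tgfb1 by 0.85 and Inhba by 0.62, while Gdf15 fell by 1.58, Lefty1 by 1.46, Bmp4 by 1.44, Acvr2b by 0.83 and Tgfbr2 by 0.67. Of 31 actin genes 13 rose and 4 fell, the same adjusted over the list alone (median 0.28, adjusted p = 0.0205, but adjusted p = 0.111 with an estimated correlation). Actn1 rose by 1.31, and Rnd3 fell by 1.62, Lasp1 by 1.08 (−0.43 with the term), Anln by 0.94 and Lima1 by 0.93. Of 27 NF-kappaB and cytokine genes 11 rose and 4 fell, or 13 and 4 adjusted over the list alone (median 0.30, adjusted p = 0.0205, but adjusted p = 0.132 with an estimated correlation), and with the brightness term the list was not called (adjusted p = 0.096). Ccl7 rose by 1.79, and Cxcl1 fell by 2.11, Il33 by 1.22 (−2.16 with the term), Tnfaip2 by 1.09 (−0.68 with the term) and Bcl3 by 0.43. Of 25 immediate-early genes 8 rose and 3 fell, or 9 and 4 adjusted over the list alone (median 0.23, adjusted p = 0.0455, but adjusted p = 0.111 with an estimated correlation). Fos rose by 1.96 and Ier3 by 1.04, Egr2 was at least 2.4-fold higher, and Dusp1 and Dusp6, which dephosphorylate MAP kinases, and Zfp36, which destabilizes cytokine mRNAs, fell by 0.87, 0.38 and 0.79. This list was not called without serum-free 1, 2 or 3, GDF11 1 or TGFB1 3 (adjusted p 0.0518 to 0.0976). The brightness term put these 4 medians at 0.35, 0.21, 0.37 and 0.18.

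Some of these single calls for TGFB1 lay near the threshold. Without 1 array the calls of Acvr2b (serum-free 1, 2 or 4 or any TGFB1 array, adjusted p 0.0587 to 0.0923), Bcl3 (serum-free 1 or 4 or any TGFB1 array, 0.0546 to 0.088), Twist2 (serum-free 2 or 4 or TGFB1 1 or 3, 0.0502 to 0.0603), Anln (serum-free 1 or 2, 0.0541 and 0.0574) and Dusp6 (TGFB1 1, 0.0561) ended. The brightness term ended those of Acvr2b (−0.08, adjusted p = 0.809), Anln (−0.19, adjusted p = 0.466) and Bcl3 (−0.33, adjusted p = 0.209) too. Under median scaling, which moved the median of all genes by 0.69 in this comparison, the values of Acvr2b, Anln, Bcl3, Dusp1, Dusp6, Lamc1, Lima1, Mmp13, Tgfbr2 and Zfp36 turned to between 0.05 and 0.57, still below that median. Tgfb1, Cdkn2b (0.97, and 0.61 with the term) and Cdkn1a (0.56) rose with TGFB1 as with GDF11, Vim did not pass (0.44, adjusted p = 0.0918, and −0.01 with the term) and neither did Myc (−0.21, adjusted p = 0.391). Cdh1 was called higher (0.90 ± 0.24, adjusted p = 0.0123), but with the brightness term its 0.25 did not pass (adjusted p = 0.285). On bright arrays alone Inhba did not pass (adjusted p = 0.159). Fstl1, a secreted BMP-binding glycoprotein, was at least 1.59-fold higher.

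The Id genes, direct BMP targets that block differentiation factors, were lower with TGFB1. Id3 fell by 1.53 (adjusted p = 0.000859), Id1 by 0.62 ± 0.15 (adjusted p = 0.00683) and Id2 by 1.18 ± 0.42 (adjusted p = 0.0427), and with the brightness term the values were −2.11, −0.97 and −2.45. With GDF11, Id3 fell by 1.35 ± 0.26 (adjusted p = 0.00543), though it did not pass with the authors' processed values (−0.42, adjusted p = 0.0651). Id1 (−0.30, adjusted p = 0.185) and Id2 (−0.13, adjusted p = 0.844) did not pass without the term but did with it (−0.54, adjusted p = 0.00155, and −0.98, adjusted p = 0.000219). On bright arrays alone, with 1 serum-free array, Id1 and Id2 stood at −0.55 and −1.01. That array, serum-free 3, held Id1 at 10.17 where the other serum-free arrays held 9.67 to 9.73. Of the 10 BMP and SMAD1/5 targets tested, 5 fell with TGFB1 and none rose, the same adjusted over the list alone. These were the 3 Id genes, Msx1 (−0.62, and −0.41 with the term) and Hey1 (−0.67), and camera did not call the list without the term (median −0.44, adjusted p = 0.247). With the term it was called for TGFB1 (median −0.37, adjusted p = 0.00371, but adjusted p = 0.0978 with an estimated correlation) and for GDF11 (−0.18, adjusted p = 0.0159, but adjusted p = 0.124 with an estimated correlation). The Id2 call for TGFB1 without the term ended without serum-free 1, 2 or 3, GDF11 3 or any TGFB1 array (adjusted p 0.0514 to 0.0864), and under cyclic loess, no background correction, no filter or the authors' processed values (0.0509 to 0.109). That of Hey1 ended without serum-free 1 or 4 or TGFB1 1, 3 or 4 (0.0578 to 0.0847) and with the term (−0.15, adjusted p = 0.605). Under median scaling Id1, Msx1 and Hey1 turned to 0.38, 0.19 and 0.21 for TGFB1, below the 0.69 by which the median of all genes moved, and array weights turned Id2 to 0.56 for GDF11 (adjusted p = 0.0391).

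**Figure D3:**
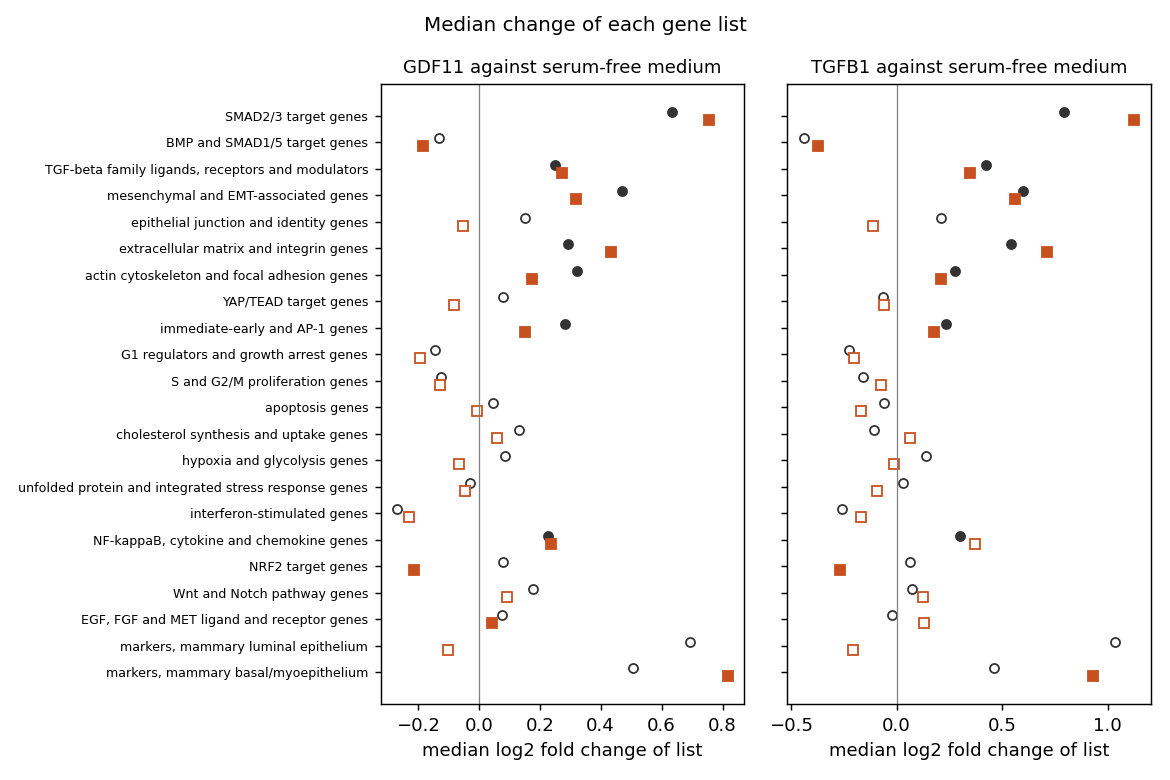
Median log2 change of each of the 22 tested lists for GDF11 and for TGFB1 against serum-free medium, as circles without and squares with the brightness term, filled where the camera adjusted p was under 0.05. SMAD2/3 targets lie highest among the called lists without the term (0.64 and 0.79) and at 0.75 and 1.12 with it, below the basal markers (0.82) for GDF11. With the term, medians change sign for both ligands for NRF2 targets, luminal markers, epithelial junction genes and hypoxia and glycolysis genes. Some other lists change sign for a single ligand.

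For TGFB1, the 15 lists that camera did not call without the term had adjusted p from 0.235 to 0.939. Medians were 0.21 for epithelial junction genes (10 rose and 8 fell of 29, or 11 and 9 adjusted over the list alone), −0.06 for YAP/TEAD targets, −0.23 for G1 and growth arrest genes, −0.16 for S and G2/M genes and −0.06 for apoptosis genes. They were −0.11 for cholesterol genes, 0.14 for hypoxia and glycolysis genes, 0.03 for unfolded protein response genes, −0.26 for interferon-stimulated genes, 0.06 for NRF2 targets, 0.07 for Wnt and Notch genes and −0.02 for EGF, FGF and MET genes. Luminal and basal markers had medians of 1.04 and 0.46. For YAP/TEAD targets, cholesterol genes, unfolded protein response genes and EGF, FGF and MET genes the test pointed against the sign of the median.

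TGFB1 was set directly against GDF11, at doses that differed, and the genes that separated them were mostly ones TGFB1 changed more. Il11 was 2.82-fold higher with TGFB1 (log2 difference 1.5 ± 0.26, SE, n = 4 per group, limma adjusted p = 0.0181) and Ass1 2.56-fold (1.36 ± 0.14, adjusted p = 0.000499). The cornified envelope gene Lce1f (1.38 ± 0.12, adjusted p = 0.000183), Prss46 (1.22 ± 0.11, adjusted p = 0.000183), Adgra1 (1.47 ± 0.15, adjusted p = 0.000367) and the muscle acetylcholine receptor gene Chrna1 (1.28, adjusted p = 0.00267) were higher too. Lce1f and Prss46 were detected on 2 of the 4 GDF11 arrays, so the sizes of these differences are uncertain. Ctsw, Pcolce2, Nfe2l3 and Chst8 were higher by 1.35, 1.34, 1.29 and 1.20. Tmprss2 was lower by −1.30 ± 0.18 (adjusted p = 0.00458), as were the epithelial differentiation gene Ivl (−1.12), Sorbs2 (−1.16), Prr15l (−1.15), BC025446 (−1.07), Kank1 (−1.03), Cmtm8 (−1.01), the prolyl hydroxylase gene Egln3 (−0.99), Nrep (−0.96) and Cavin2 (−0.91).

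In all, 76 genes passed (0.832%), 40 higher and 36 lower with TGFB1, and 808 had an unadjusted p under 0.05. The groups did not overlap for 10.5% of genes, where chance gives 2.86%. TGFB1 arrays held a mean of 36.3 ± 1.34 beads per probe and GDF11 arrays 39.3 ± 0.60 (SD, n = 4 each, two-sided exact permutation p = 0.0286). All 76 were among the 229 genes called with the brightness term, and the bright arrays alone gave 536 calls. The count with the term was 110 or 146 without GDF11 2 or 3 and 150 without TGFB1 3. The count was 31 or 29 without GDF11 2 or 3 and 27, 24, 19 and 31 without TGFB1 1, 2, 3 or 4. At least 1 omission among those arrays or GDF11 4 ended each of the calls of Il11, Chst8, Nfe2l3, Ivl, BC025446, Kank1, Cmtm8, Nrep and Cavin2 (adjusted p 0.05 to 0.0989), while those of Lce1f, Prss46, Adgra1, Ass1, Chrna1 and Tmprss2 held under each such omission. With the authors' processed values Ivl, BC025446 and Cavin2 did not pass (adjusted p 0.13 to 0.366).

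The SMAD2/3 targets lay higher with TGFB1 than with GDF11: of 29 tested, 4 were called higher and none lower, or 8 and 1 adjusted over the list alone (median 0.16, camera adjusted p = 4.58e-05, but adjusted p = 0.12 with an estimated correlation). These were Timp3 (1.20), Snai1 (1.12 ± 0.20, adjusted p = 0.0169), Col7a1 (0.95) and Bhlhe40 (0.70). Matrix and integrin genes had 3 higher and none lower of 29, or 9 and 2 adjusted over the list alone, namely Timp3, Col7a1 and Itga5 (0.82). The median of these 29 was 0.28 (adjusted p = 4.58e-05, but adjusted p = 0.12 with an estimated correlation). Of 22 mesenchymal genes, Snai1 and Itga5 were the 2 higher and none was lower, the same adjusted over the list alone (median 0.24, adjusted p = 0.00217, but adjusted p = 0.173 with an estimated correlation). The term put these 3 medians at 0.27, 0.35 and 0.12. Members that did not pass included the matrix genes Mmp9 (0.59, adjusted p = 0.337) and Timp1 (0.50, adjusted p = 0.0681, and 0.0201 with the term) and, from the mesenchymal list, Fstl1 (0.53, adjusted p = 0.28). Inhba was higher with TGFB1 (0.80 ± 0.13, adjusted p = 0.0122). These single calls ended without GDF11 2, 3 or 4 or any TGFB1 array for Timp3 (adjusted p 0.0664 to 0.155), Col7a1 (0.0708 to 0.164), Itga5 (0.061 to 0.137) and Bhlhe40 (0.0582 to 0.121), without TGFB1 1, 3 or 4 for Snai1 (0.0555 to 0.0789), and without TGFB1 1, 2 or 3 for Inhba (0.052 to 0.0575).

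Several direct targets did not pass between the ligands: Pmepa1 (0.02, adjusted p = 0.981), Skil (−0.15, adjusted p = 0.828), Id3 (−0.18, adjusted p = 0.855), Id1 (−0.32, adjusted p = 0.556) and Id2 (−1.05 ± 0.42, adjusted p = 0.459). Id1 and Id2 passed with the brightness term at −0.44 (adjusted p = 0.0104) and −1.47 (adjusted p = 4.1e-05). Cdh1 (0.19), Tgfb1 (0.10), Cdkn2b (0.10), Cdkn1a (0.09), Vim (−0.06) and Myc (−0.06) did not pass. The 19 other lists tested between the ligands had camera adjusted p of 0.132 to 0.91 without the term. With it, BMP targets (median −0.15, adjusted p = 0.00249, but adjusted p = 0.087 with an estimated correlation), G1 and growth arrest genes (−0.08, adjusted p = 0.0377, but adjusted p = 0.22 with an estimated correlation) and apoptosis genes (−0.06, adjusted p = 0.0377, but adjusted p = 0.153 with an estimated correlation) were called as well. Median scaling moved the median of all genes by 0.29 in this comparison and gave 32 calls, 96.9% of them higher with TGFB1.

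The 2 responses overlapped: 870 genes, Lmcd1, Il11, Cldn4, Dio3 and Depp1 among them, were called in the same direction for both ligands, 407 higher and 463 lower, and none in opposite directions by limma. Independent lists of these sizes would share 68.7 higher and 87.7 lower genes. Both comparisons use the same serum-free arrays, so 50 simulations of unchanged groups against shared controls were made, with the measured brightness shift on the arrays. These shared 0 genes (median, at most 1). Groups with no treatment effect give almost no calls in either comparison, so this count cannot show how far shared controls raise the overlap. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.941 against a simulated 0.913, and a covariance of 0.236 against a simulated 0.12. With 2 serum-free arrays given to each ligand, over the 6 ways to do so, 283 to 652 genes were shared, r was 0.723 to 0.798 and the covariance 0.185 to 0.223. With the brightness term 837 genes were shared, 455 higher and 382 lower (independent 40.7 and 34.9), and 309 without GDF11 1. Pearson r was then 0.908 against a simulated 0.652, and the covariance 0.142 against a simulated 0.0199. The split controls with the term gave 586 to 618 shared genes, r of 0.686 to 0.709 and a covariance of 0.125 to 0.135. The shared count without the term was 558, 501, 2688 and 493 without serum-free 1, 2, 3 or 4, and 2970, 508, 476 and 437 without GDF11 1, 2, 3 or 4. The 2688 and 2970 again lack the only bright serum-free or the only dim GDF11 array, so they cannot be read as a larger overlap.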

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

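The tests chosen only after the result was seen were those of compression and of swapped labels for the dim arrays, all 3 for the fall in TGFB1 calls, and every value with the brightness term. The other tests below were set earlier.

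Serum-free 3 had a mean raw intensity of 283 where the other serum-free arrays had 149 to 165, and 48.6% of its probes were detected where they had 42.4% to 42.7%. Among the genes examined singly, 45 of 411 gene and group sets held an array far from the other 3, where chance gives about 1 in 20. Serum-free 3 was that array in 12 of them and GDF11 1, the dim array of its group, in 19. The genes were in part chosen from these data, Krt8 and Krt18 after their values were seen. The 1 in 20 holds for unselected genes, so the excess may in part come from this choice.

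The first pattern is the split of the arrays into 4 dim and 8 bright ones, with 4494 genes shifted, Krt8 by 1.03 and Id2 by 1.69 among them. Compression of signal on the dim arrays is argued against as the whole cause. With cyclic loess, which removes trends with signal, the number of genes shifted was 54.7% of that under median scaling, and with quantile normalization 60.6%. An earlier test, the 0.323% of the shift's variance that mean level explains, is set by quantile normalization and decides nothing. Swapped labels of GDF11 1 and serum-free 3 are argued against, because the 29 SMAD2/3 targets lay a median 0.95 ± 0.18 (bootstrap SE) higher on GDF11 1 than on the dim serum-free arrays. A probe-level effect of RNA quality or labelling stays open as a candidate cause: shifts of 2 probes of one gene correlated at 0.186 where TGFB1 effects of the same 2490 pairs correlated at 0.916, both freed of noise, a difference of −0.73 (SE 0.0259). No biological explanation was tested, as the design gives none for these arrays.

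The second pattern is the fall from 3140 to 1448 genes called for TGFB1 against serum-free medium once brightness is a term, the calls of Cdh1, Krt8 and Krt18 among those that ended. Wider standard errors are argued against for the lost genes as a set, because their median SE went from 0.18 to 0.15. The lost genes kept a median 0.375 of their log2 change (median size 0.64 before and 0.24 after), and the kept genes held 0.891. That drop is partly built in, as the lost genes were picked for losing the call. In simulations with no brightness shift, the term alone cut recovery of TGFB1 changes of 0.5 from 44.8% to 22.4%. Unequal numbers of dim arrays, 3 in serum-free medium and none with TGFB1, stay open: with the term fitted on the serum-free and TGFB1 arrays alone, 89.0% of 2846 lost calls and 56.0% of 693 kept calls had the sign of the bright minus dim difference among the GDF11 arrays. Of all tested genes, called or not, 73.0% had that sign. The 89.0% fell just short of the 90% set for this test. An earlier form, with the GDF11 arrays in the fit as well, gave 92.5% of 2024 lost calls but is void, because those arrays then helped to pick the genes. Simulating the imbalance alone gave 0 calls (median of 20 simulations), but it left out the treatment effects, and the simulation with changed genes gave 59 false calls, so the imbalance and the TGFB1 effect cannot be told apart for the lost calls.

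In other splits of the 8 arrays compared, 1 of 35 splits, the real one, gave as many calls for TGFB1 against serum-free medium (3140, and 1448 with the term) and for TGFB1 against GDF11 (76, and 229 with the term). The highest of the others was 0 calls each time. This argues against chance without excluding it, since 1 of 35 is the smallest share the test allows. It cannot tell the ligand from differences in brightness or beads between the groups. For GDF11 against serum-free medium 2 of 35 splits gave at least 907 calls, which does not argue against chance: the split of the 4 dim from the 4 bright arrays gave 4716, which points to a structure of the samples. With the brightness term the real split was the 1 of 34 that gave 953 calls, the highest other was 0, and 1 split could not be fitted.

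On serum-free 3 the log2 intensities far from the other 3 arrays were Actn1 11.26, Ass1 5.55, Id1 10.17, Itgb4 9.41, Kitl 5.29, Krt8 13.69, Nuak2 9.14, Pmepa1 4.81, Ppp1r3c 5.36, Slc7a11 5.37, Tgfbr1 10.30 and Wnt7a 5.84. On GDF11 1 they were Anln 9.60, Bcl2l11 8.30, Bmf 8.17, Cald1 6.05, Cdh1 9.89, Dram1 8.81, Fas 7.84, Fzd7 6.51, Gclc 4.28, Id1 9.17, Id2 9.07, Il33 6.27, Itga6 6.21, Kitl 7.23, Krt18 11.64, Krt8 12.88, Pfkfb4 6.79, Rhob 9.31 and Wnt7a 7.63. The other arrays far from their group were GDF11 2 for Cmtm8 (9.26), Inhba (6.38) and Timp1 (8.59) and GDF11 4 for Bcl3 (6.27). In serum-free medium they were replicate 1 for Pcolce2 (5.56), replicate 2 for Pdgfb (8.51) and replicate 4 for Lamb3 (8.46) and Mmp9 (5.07). With TGFB1 they were replicate 1 for Gclm (10.83), replicate 2 for Gclc (5.07), replicate 3 for Cmtm8 (7.53) and Shh (4.45), and replicate 4 for Chst8 (9.21) and Il33 (6.73).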

How the results depend on the processing

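The tests chosen only after the result was seen were those with the brightness term, with bright or dim arrays alone, and the term joined with a replicate block or with single arrays left out. Signal over background limited the test to 12680 of 25697 probes. Of the 32 settings, the other list tests were not applied to single genes, and the 1.5-fold minimum was applied neither to single genes nor to lists. Called named genes such as Lmcd1 and Dio3 gave 5661 values, of which 5296 kept direction and call, 348 lost the call and 17 turned. Uncalled ones gave 1276 values, of which 98 gained a call. Called lists gave 527 values, 469 kept and 58 lost, and uncalled lists 1516, of which 46 gained a call. Counted by result, 113 of the 204 gene calls and 3 of the 17 list calls held under every setting tried for them. The cause of the changes below was not tested unless the setting uses fewer arrays, genes or a stricter threshold. Genes called for GDF11 against serum-free medium (907) were 190 with median scaling, 352 with only the groups compared, 4485 with array weights, 357 at an adjusted p under 0.01, 563 on bright and 6 on dim arrays, and 444 to 3367 leaving out 1 array. For TGFB1 against serum-free medium (3140) they were 4882 with array weights, 1372 at 0.01, 1448 with the term, 1558 on bright arrays, 1048 with term and replicate block, and 2046 to 4453 leaving out 1 array. For TGFB1 against GDF11 (76) they were 32 with median scaling, 128 with cyclic loess, 674 with array weights, 20 at 0.01, 229 with the term, 536 on bright arrays, 201 with term and block, and 19 to 109 leaving out 1 array, the highest without GDF11 1. Genes shared by both ligands (870) were 190 with median scaling, 351 with only the groups compared, 3995 with array weights, 355 at 0.01, 545 on bright arrays, and 437 to 2970 leaving out 1 array. The correlation of fold changes was 0.896 on bright arrays and 0.913 to 0.958 leaving out 1 array. Called lists for GDF11 (7) were 4 with the strict filter, 3 with an estimated correlation, 14 with fry, 11 with the term and 6 to 8 leaving out 1 array. For TGFB1 (7) they were 3 with median scaling, 4 with the strict filter, 3 at 0.01, 1 with an estimated correlation, 17 with fry and 6 to 7 leaving out 1 array, and for TGFB1 against GDF11 (3) they were 0 with an estimated correlation, 6 with the term, 7 on bright arrays, 6 with term and block and 3 leaving out any array. With the term and 1 array left out the counts were 313 (without GDF11 1) to 1065, 975 to 1580, 110 (without GDF11 2) to 313, and 309 (without GDF11 1) to 906 shared. A replicate block alone gave 868, 3299 and 57 calls and ended those of Timp3 and Col7a1 between the ligands (adjusted p = 0.0831 and 0.104). The authors' processed values gave 873, 2848 and 109. Calls were higher in the first group named in 92.6%, 97.5% and 96.9% of cases with median scaling, against 48.2%, 45.7% and 52.6%. Directions turned with median scaling for Llgl2 (0.0376) and Tgfbr2 (0.0927) with GDF11, and with TGFB1 for Id1 (0.38), Lima1 (0.0524), Acvr2b (0.13), Anln (0.0480), Bcl3 (0.47), Dusp1 (0.11), Dusp6 (0.57), Hey1 (0.21), Lamc1 (0.40), Llgl2 (0.00929), Mmp13 (0.11), Msx1 (0.19), Tgfbr2 (0.32) and Zfp36 (0.18). Others that turned were Id2 with GDF11 and array weights (0.56), Acvr2b with TGFB1, term and block (0.0270), and the NRF2 list with TGFB1 and the term (−0.27), bright arrays (−0.20) or term and block (−0.33) and against GDF11 on bright arrays (−0.0767). A chip block was not run, as the files name no chip.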

Other observations

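All values with the brightness term were chosen only after the split of the arrays was seen, as were the genes named here that the report does not name. The tests of a single factor and of a signal ceiling were set before their results.

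Genes of growth arrest and cell death moved on both sides with the 2 ligands, within lists that camera did not call against serum-free medium. Of 28 G1 and growth arrest genes 4 rose and 5 fell with GDF11, or 5 and 8 adjusted over the list alone, and 4 rose and 9 fell with TGFB1, or 6 and 11. Of 28 apoptosis genes 3 rose and 3 fell with GDF11, or 3 and 4 adjusted over the list alone, and 4 rose and 8 fell with TGFB1, the same adjusted over the list alone. Gadd45a, a stress-induced growth arrest gene, rose by 1.65 ± 0.11 with GDF11 and 1.91 ± 0.11 with TGFB1 (SE, n = 4 per group, limma adjusted p = 7.54e-07 and 7.35e-08), and Gadd45g by 0.97 and 1.15. The cyclin gene Ccnd2 fell by 1.24 and 1.94. Ddit4, which restrains mTORC1, rose by 1.84 and 2.12. The BH3-only death genes went apart: Bmf (1.12 and 1.18) and Bcl2l11 (1.07 and 1.01) rose, while Bbc3 (−0.88 and −1.03) and the death receptor gene Fas (−0.99 and −1.34) fell. The GDF11 call of Fas ended without serum-free 1 or 2 or GDF11 2, 3 or 4 (adjusted p 0.0518 to 0.0595), and that of Bbc3 on bright arrays alone (0.0652). Of 18 EGF, FGF and MET genes 5 rose and 3 fell with GDF11, or 5 and 5 adjusted over the list alone, and 6 rose and 5 fell with TGFB1, the same adjusted over the list alone. Among growth factor genes, Pdgfa (1.72 and 2.40) and the EGF receptor ligand Areg (0.97 and 1.10) rose, and Nrg1 (−0.89 and −1.62) and the receptor Fgfr2 (−0.93 and −1.33) fell. Of 21 Wnt and Notch genes 4 rose and 1 fell with GDF11, or 6 and 2 adjusted over the list alone, and 8 rose and 3 fell with TGFB1, or 9 and 3. The Notch ligand Jag1 (0.82 and 1.34) and Wnt7a (1.07 and 1.38) rose, and the Wnt receptor Fzd7 fell by 0.66 and 1.18. All of these genes kept their call with the brightness term, but it moved Fas to −0.56 and −0.70 and, with TGFB1, Bbc3 to −0.68 and Bcl2l11 to 1.60.

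Some gene groups that camera did not call on all arrays without the brightness term were called with it. NRF2 targets were then called lower with GDF11 (median −0.21, 7 of 24 fell and none rose, or 11 and 2 adjusted over the list alone, adjusted p = 0.00132, but adjusted p = 0.136 with an estimated correlation) and with TGFB1 (−0.27, 10 fell and 1 rose, or 10 and 2 adjusted over the list alone, adjusted p = 0.00302, but adjusted p = 0.189 with an estimated correlation). Slc7a11, the cystine importer, was lower by −0.91 with each ligand, and the glutathione synthesis gene Gclc by −1.61 and −2.31, while its partner Gclm was higher with TGFB1 (0.69, adjusted p = 0.000933). Without the term the NRF2 medians were 0.08 and 0.06, Gclc stood at −0.98 (adjusted p = 0.104) and −1.36, and Gclm at 1.09 with TGFB1. Basal markers were called higher with both ligands (medians 0.82 and 0.93, 4 of 7 rose each time, the same adjusted over the list alone except 1 fall with TGFB1, adjusted p = 0.00683 and 0.00444, but adjusted p = 0.101 and 0.102 with an estimated correlation). Krt14 stood at 0.82 and 1.49, Egfr at 1.05 and 1.22, Itga6 at 0.94 and 1.08 and Itgb4 at 0.50 and 0.85, where without the term Krt14 stood at 0.50 (adjusted p = 0.18) and 1.02, Itga6 at 1.52 and 1.95 and Itgb4 at 0.14 (adjusted p = 0.654) and 0.32 (adjusted p = 0.234). For GDF11 the basal median was 0.36 on bright arrays, with 1 serum-free array, and 1.00 on dim arrays, with 1 GDF11 array. For TGFB1 it was 0.75 on bright arrays. The only bright serum-free array, serum-free 3, also weighs on the brightness term, so the bright arrays are not a separate check of it. Epithelial junction genes were not called with the term (medians −0.05 and −0.11): of 29, 2 rose and 2 fell with GDF11, or 3 and 4 adjusted over the list alone, and 3 rose and 7 fell with TGFB1, or 5 and 7. With TGFB1 Cldn4, which was not detected in serum-free medium, was higher. Ppl, a cytolinker of the cornified envelope, was lower (−1.30), and so was Llgl2, a polarity gene (−0.67, and 0.01 under median scaling without the term). Genes for EGF, FGF and MET ligands and receptors were called for GDF11 with the term (median 0.04, 6 of 18 rose and 2 fell, or 7 and 3 adjusted over the list alone, adjusted p = 0.0373, but adjusted p = 0.133 with an estimated correlation).

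The third pattern is that the GDF11 response resembled a smaller TGFB1 response: with the term, 759 of the 837 shared genes changed more with TGFB1. Both changes share the serum-free arrays and the fitted brightness shift, however. Simulations of unchanged groups that held this shift gave r = 0.652 with the term. One response scaled by a single factor is argued against, since 20 genes, 14 of them detected on all 12 arrays, deviated by limma from the fitted factor of 0.674 (786 at an unadjusted p under 0.05), and 18 at the factor between 0.5 and 1 with the fewest, 0.7. Of those detected on all arrays, some responded alike to both ligands, as Lmcd1 (3.91 and 4.22), Tgfbr1 (1.88 and 1.92), Dram1 (2.44 and 2.71), Junb (1.32 and 1.15), Cdh6 (1.45 and 1.36) and Nuak2 (1.26 and 1.16). Others responded mainly to TGFB1, as Pfkfb4 (0.68 and 1.97) and Id2 (−0.98 and −2.45). Nrep (0.30, adjusted p = 0.246, and −0.59, adjusted p = 0.0334) and Inhba (−0.25, adjusted p = 0.285, and 0.52, adjusted p = 0.0309) were called for TGFB1 alone, with GDF11 values of the other sign that did not pass. Paqr7 (0.51, adjusted p = 0.0107, and −0.003, adjusted p = 0.993) was called for GDF11 alone. That call ended on bright arrays alone, with 1 serum-free array, and under median scaling (adjusted p = 0.18). A signal ceiling is argued against for the 9 deviating genes not called between the ligands, whose median TGFB1 level lay at the 86.6th percentile of tested genes, the highest at 98.7. The dose and the identity of the ligand differed together, so both stay open as untested sources that could underlie the difference. The groups also held unequal numbers of bright arrays, 1 in serum-free medium, 3 with GDF11 and 4 with TGFB1. An error in the fitted brightness shift would therefore enter the TGFB1 change more than the GDF11 change, and its part was not tested.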
